A study of Mus musculus with 6 samples.

How the data were processed

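The data were 6 MARS-seq libraries of sorted mature medullary thymic epithelial cells (mTEChi) of NOD mice aged 4.5 weeks, 3 labelled Aire+/+ and 3 labelled Aire−/−. Per the labels' protocols, thymi were dissociated with Liberase TH and DNase, the cells were sorted, RNA was taken up with Dynabeads, and libraries were built by MARS-seq, which adds a molecular identifier to each captured 3′ end. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 and the genome build mm10, without their roles. The gene annotation, the strand setting and the handling of UMIs and of reads that match several genes are not given in the sources used here.

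One table for the whole series was used. Its UMI counts per gene symbol are raw counts deposited by the authors, per the file headers. The table also holds normalized counts, a signal that the authors made by dividing the counts of each library by 1 size factor (tested on the table: the ratio was constant in every library), and regularized log2 values by the authors, which were not used. The log2 fold changes of Aire+/+ over Aire−/−, the p-value and adjusted p-value of each gene and a yes or no selection are the authors' own DESeq2 results, per the file headers. The deposited adjusted p-values equal Benjamini-Hochberg values over all 15643 genes, and the 1474 selected genes are those with an adjusted p up to 0.05, at least 2-fold change and a mean normalized count of at least 5. Every gene reaches 6 UMIs in at least 1 library, so the authors' table holds no gene below that. No row lacks a gene name, no mitochondrial gene is in the table, and no per-sample column was left without a sample.

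Library totals ran from 1014581 to 2887321 UMIs. A count of 0 allows up to 3 UMIs, which is 1.04 to 1.10 CPM of the library total in the Aire+/+ libraries and 1.53 to 2.96 CPM in the Aire−/− libraries. Intervals and floors cover counting error only. For a gene with 0 UMIs in all libraries of one genotype, the fold is a lower bound against 3 UMIs over that group. For 1 to 3 UMIs, the ratio is given with an exact Clopper-Pearson counting interval at 95% confidence. Levels are CPM scaled by edgeR's TMM factors, as mean ± SD over 3 libraries.

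The genotypes were compared with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood tests (glmQLFit, glmQLFTest) on the counts with TMM scaling, the genotype as the only term, filterByExpr with min.count 10 and Benjamini-Hochberg adjustment, with an adjusted p of 0.05 as the threshold. The filter kept 11956 genes, and the common dispersion was 0.0241. The numbers of the libraries differ between genotypes and pair none of them. All adjusted p-values of single genes are edgeR's unless the authors' deposited table is named. Standard errors were taken from the fold change and its F statistic.

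Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, and adjusted by Benjamini-Hochberg over the 30 lists with 3 or more tested members. Beside it stand camera with an estimated correlation, and fry, which is two-sided. The 31 lists, the tests, the rule for named genes and the alternatives, apart from those named as added, were fixed in advance. Named genes were Aire, every enamel gene in the table, the 10 most negative and 10 most positive log2 fold changes among called genes whose libraries do not overlap and whose mean is at least 5 UMIs in the higher genotype (unnamed gene models left out), and up to 3 tested members of each other list with the smallest p, of which 1 gene is not reported here. Other list members, genes of the chromosome 5 and Aire regions and genes of the closing section were named after their values were seen.

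Genes detected at equal depth were counted after thinning each library to the smallest total without replacement (mean of 20 seeded draws) and compared with an exact two-sided permutation test. Tested genes were ranked by mean CPM over all 6 libraries and parted into 4 groups of 2989. Positions come from a GENCODE annotation of the mouse build that mm10 names. It holds 15363 of the 15643 symbols, 22 of them given to more than 1 gene. The last 300 nt of the transcripts of named genes were searched against all transcripts with blastn 2.17.0, and matches of at least 80 nt and 90% identity were kept as near-identical copies.

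The test steps were checked on simulated counts of these libraries, with genes changed by known amounts. For the comparison of Aire−/− with Aire+/+, edgeR on 11754 simulated genes recovered 95% of genes made 8-fold lower, 70% of those 4-fold lower, 35% of those 2-fold lower, 55% of those 2-fold higher and 100% of those 4-fold higher (40 genes each), with 11 false calls among 153. Of 100 simulated lists without change, 2 had a p under 0.05 by camera with the preset correlation, 0 with an estimated correlation and 4 by fry. Simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.483. This check therefore cannot show how often the preset correlation errs on lists of correlated genes.

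The alternatives were RLE and upper-quartile scaling, library totals alone, no filter, min.count 3 and min.count 30, DESeq2 1.42.0, limma-voom, a 2-fold threshold, an adjusted p of 0.01, each library left out, a split by Xist as covariate (above 5 CPM, a level set after seeing the data), other detection rules, and camera with an estimated correlation or fry for the lists. Thinning every library to the smallest total, leaving out Aire+/+ 753 and Aire−/− 746 together, detection from 6 UMIs, thinning to equal effective sizes (total times TMM factor) and ranking by the mean of the higher genotype were added after seeing the data. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.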

Results

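Gene expression was measured in mature medullary thymic epithelial cells, the MHC class II-high fraction (mTEChi) of the epithelium that displays proteins of peripheral tissues to developing T cells. The cells were sorted from thymi of NOD mice aged 4.5 weeks, a strain prone to autoimmune diabetes. Libraries were made by MARS-seq, which counts unique molecular identifiers (UMIs) near the 3′ ends of transcripts. There were 6 libraries, 3 labelled Aire+/+ (numbers 745, 750 and 753) and 3 labelled Aire−/− (numbers 746, 748 and 749). Aire encodes a transcriptional regulator whose loss causes autoimmune polyendocrine syndrome type 1 (APS1). The series title links that syndrome and celiac disease to an autoimmune defect of tooth enamel, so the comparison asks which transcripts, enamel proteins among them, differ between these cells with and without Aire. The deposited table held 15643 genes. Its UMI totals were 2736932, 2839488 and 2887321 in the Aire+/+ libraries and 1014581, 1960802 and 1824232 in the Aire−/− libraries. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom between 3.02 and 6.83, and each was counted as 1 replicate. The labels do not say whether each number was a separate animal or whether libraries shared a litter or preparation, so p-values measure the spread between these libraries.

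Transcripts assigned to Aire were more abundant in the libraries labelled Aire−/−. Aire stood at 6290, 6783 and 7290 UMIs in the Aire+/+ libraries and at 4772, 8298 and 8372 UMIs in the Aire−/− libraries. As CPM, the UMIs of a gene scaled to a common library size, Aire was at 2250 ± 192 against 4827 ± 333 (SD, n = 3 each), a log2 fold change of 1.10 with a standard error of 0.14 (edgeR adjusted p = 7.76e-05). Aire lies on chromosome 10 at positions 78030022 to 78043610 (mm10, minus strand), and a 3′ tag counts the end of the transcript. The labels do not give the deleted part of the allele, and a 3′ tag outside that part checks nothing about the genotype. Directions below therefore rest on the labels, and "lower" and "higher" describe the libraries labelled Aire−/− relative to those labelled Aire+/+. Dnmt3l, a DNA methylation cofactor whose gene overlaps that of Aire on the opposite strand (positions 78041947 to 78063622), rose by a log2 fold change of 2.27 (edgeR adjusted p = 5.21e-07). The overlap, positions 78041947 to 78043610, lies at the 5′ ends of both genes, away from the 3′ ends that the libraries count.

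Transcripts of pancreatic enzymes, odorant-binding proteins and other proteins of peripheral tissues were among the strongest decreases in the libraries labelled Aire−/−. Ctrb1, a pancreatic protease precursor, was at 149 ± 22.9 CPM in the Aire+/+ libraries and had 0 UMIs in every Aire−/− library, which is at least 222-fold lower when 3 UMIs over the Aire−/− group are taken as the floor. Pla2g1b, a phospholipase secreted by the pancreas, was at least 96.6-fold lower, Obp2a, an odorant-binding protein, at least 151-fold lower, and Hbb-y, an embryonic haemoglobin chain, at least 98.0-fold lower. Hamp, which encodes the iron-regulating hormone hepcidin, went the other way, from 168 ± 22.5 to 1103 ± 98.0 CPM (log2 fold change 2.71, standard error 0.15). Among 11956 genes tested, edgeR called 1450 lower and 1027 higher at an adjusted p of 0.05, and 9479 were not called.

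Decreases were larger than increases. The median log2 fold change was -2.18 among genes called lower and 0.84 among genes called higher, against -0.02 over all tested genes. A fitted change of at least 2-fold was found for 1201 lower and 359 higher genes, and one of at least 8-fold for 557 lower and 5 higher genes, of which 537 and 4 also reached 8-fold by their pooled UMIs with 3 UMIs as the floor of each genotype. Of the genes called lower, 184 had 0 UMIs in all 3 Aire−/− libraries. Over all genes of the authors' deposited table, 857 were at 0 in all Aire−/− libraries and 2 in all Aire+/+ libraries. These counts were taken without thinning, and the Aire+/+ group held 8463741 UMIs against 4799615 in the Aire−/− group. The table also leaves out genes below a minimum count in every library, which deeper libraries reach more easily. The size of this contrast therefore cannot be taken as that at equal depth. The libraries of the genotypes did not overlap for 2440 of the 2477 called genes and for 4362 of the tested genes (36.5%, where chance gives 10% for 3 against 3). The first principal component of log2 CPM separated the genotypes and held 72.4% of the variance, and the second held 13.8%. The authors' deposited table selects 1117 genes as higher in Aire+/+ and 357 as higher in Aire−/−. Of the 1014 and 346 of these that were tested, 1014 were called lower and 341 higher.

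The split between lower and higher calls depended on the libraries and on the scaling. Without the Aire+/+ library 745 there were 632 higher genes and without 753 there were 618, and scaling by library totals alone moved the median of all genes to -0.22 and gave 2048 lower (78.3% of calls, against 58.5%) and 567 higher. Gapdh, a glycolytic enzyme present in every cell, was nearly missing from 753 (90 UMIs) and 746 (28 UMIs) but had 2245 to 4166 UMIs in the other 4 libraries, and with both left out 1177 genes were lower and 652 higher.

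**Figure D1:**
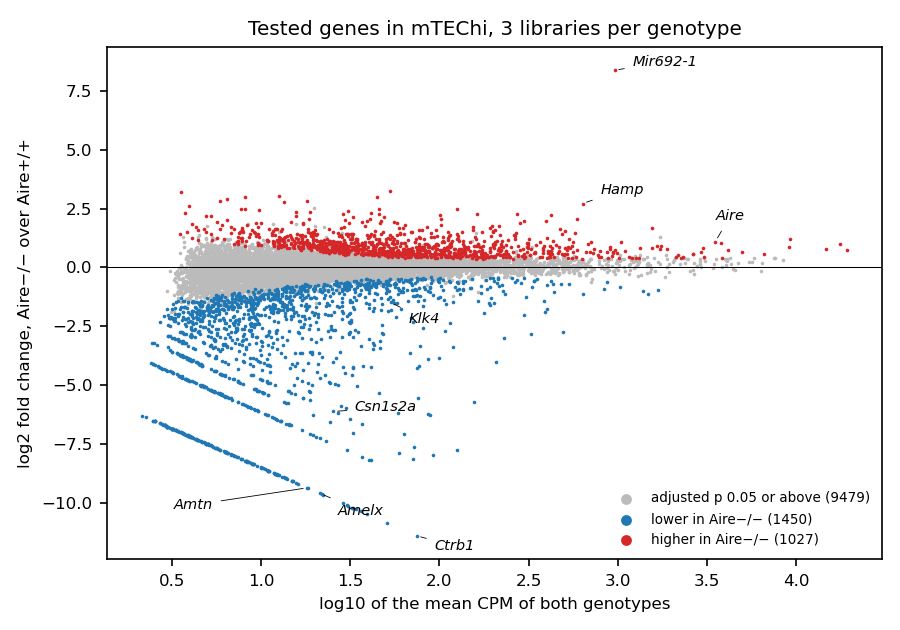
Log2 fold change of the Aire−/− over the Aire+/+ libraries (vertical axis) against the log10 of the mean CPM of both genotypes (horizontal axis) for each of the 11956 tested genes, as fitted by edgeR, with the 1450 genes called lower and the 1027 called higher in blue and red. The lowest line of points holds genes with 0 UMIs in every Aire−/− library, whose fitted values depend on a prior count and are no bounds, and Mir692-1 stands alone at 8.37.

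The 10 genes with the most negative fold changes under the rule for named genes all had 0 UMIs in the libraries labelled Aire−/−. Besides Ctrb1 (chromosome 8, positions 111686519 to 111691010), Obp2a, Hbb-y and Pla2g1b, they were Gstm3, a glutathione transferase (at least 117-fold lower), Mucl2, a mucin-like protein (at least 108-fold), Ccl1, a chemokine (at least 101-fold), Cytl1, a secreted cytokine-like protein (at least 91.5-fold), Calb2, the calcium-binding protein calretinin (at least 89.8-fold), and Saa2, an acute-phase protein (at least 85.0-fold). Their levels in the Aire+/+ libraries ran from 57.3 ± 24.2 CPM for Saa2 to 149 ± 22.9 CPM for Ctrb1, and the edgeR adjusted p of the least significant, Saa2, was 1.75e-05. The last 300 nt of Gstm3 match Gstm1 at 90.6% identity and those of Saa2 match Saa1 at 93.4%, so reads may have been divided between these copies.

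The 10 genes with the most positive fold changes were Mir692-1, Serpina9, Lrit2, Tafa1, H2ac4, Cr2, Hamp, Gltpd2, Olfr1136 and Unc93a. Mir692-1, a microRNA gene on chromosome 17 at positions 6895229 to 6895337, had 14, 25 and 13 UMIs in the Aire+/+ libraries and 2299, 3657 and 2348 in the Aire−/− libraries (log2 fold change 8.37, standard error 0.29, edgeR adjusted p = 6.63e-09). Over 93 of its 109 nt it matches the ferritin light chain transcript Ftl1 at 95.7% identity, and Ftl2-ps, Gm12164 and Gm15590, which are not in the table, at 96.8% to 97.8%, so the counts cannot be assigned to the microRNA gene. Serpina9, a serine protease inhibitor, rose from 10.2 ± 2.83 to 95.9 ± 18.4 CPM (log2 fold change 3.24). Cr2, complement receptor 2, rose by 2.79 and H2ac4, a histone H2A, by 2.83 on the log2 scale. The smallest of these increases, that of Unc93a, was 2.47 with an edgeR adjusted p of 4.52e-06. Hamp (chromosome 7, positions 30942368 to 30944032) matches Hamp2 at 90.9% identity and Unc93a matches Unc93a2 at 98.0%, so these are uncertain between copies.

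Enamel proteins were among the transcripts that fell. Amelx, which encodes amelogenin, the main protein of the enamel matrix (chromosome X, positions 169176114 to 169187200), had 111, 164 and 112 UMIs in the Aire+/+ libraries, or 42.7 ± 9.94 CPM, and 0 in each Aire−/− library, at least 63.7-fold lower (edgeR adjusted p = 4.76e-06). Amtn, amelotin (chromosome 5, positions 88376108 to 88385916), stood at 36.3 ± 11.8 CPM and 0 UMIs, at least 54.0-fold lower (edgeR adjusted p = 1.79e-05). Klk4, a protease that clears the enamel matrix (chromosome 7, positions 43881160 to 43885804), fell from 78.2 ± 4.07 to 28.1 ± 1.06 CPM, a log2 fold change of -1.48 with a standard error of 0.15 (edgeR adjusted p = 2.25e-05). Tuft1, tuftelin (chromosome 3, positions 94612757 to 94658872), was at 9.62 ± 2.67 and 9.61 ± 1.21 CPM and was not called (log2 fold change 0.02, standard error 0.32, edgeR adjusted p = 0.971).

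The other 5 enamel genes in the table were below the count filter and carry no test. Ambn, ameloblastin (chromosome 5, positions 88455991 to 88468531), had 14, 10 and 8 UMIs in the Aire+/+ libraries and 0 in the Aire−/− libraries, at least 5.26-fold lower. Odam, secreted by ameloblasts (chromosome 5, positions 87885029 to 87894174), had 25 UMIs against 0, at least 4.11-fold lower. Acp4, an acid phosphatase mutated in inherited enamel defects (chromosome 7, positions 44252148 to 44257378), had 27 against 0, at least 4.44-fold lower. Gm17660, listed as the secretory calcium-binding phosphoprotein Scpppq1 (chromosome 5, positions 104070064 to 104077608), had 14 against 0, at least 2.30-fold lower. Mmp20, the main protease of the secretory stage (chromosome 9, positions 7628231 to 7674979), had 22 UMIs against 2, a ratio of 5.43 with an exact 95% counting interval of 1.34 to 47.6. Enam and Odaph, the other members of the list, were not analysed here.

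Of the 11 genes listed as enamel matrix and enamel proteases, 9 were in the table, 4 were tested and 3 fell, the same count as adjusted over the list alone. Their median log2 fold change was -5.42, or -3.62 with genes at 0 set to their bounds. The set test camera gave an adjusted p of 0.000762 with the preset correlation, and the adjusted p = 0.0955 with an estimated correlation. With a looser filter (min.count 3) 8 members were tested and 6 fell. In the authors' deposited table the log2 fold changes of Aire+/+ over Aire−/− were 8.37 for Amelx, 8.14 for Amtn and 1.47 for Klk4, and these 3 and Aire were selected there. Ambn (4.77), Odam (4.42) and Acp4 (4.53) had adjusted p of 0.00983, 0.0268 and 0.0202 in that table and were not selected, nor were Mmp20 (2.39, adjusted p = 0.25), Gm17660 (3.58, 0.167) and Tuft1 (-0.025, 0.984).

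**Figure D2:**
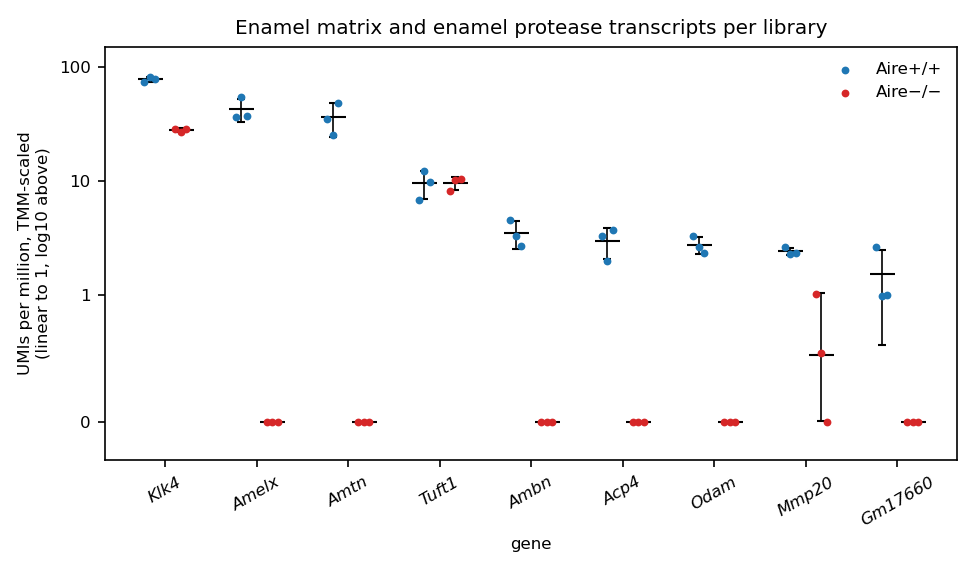
CPM scaled by TMM (vertical axis, linear up to 1 and log10 above), of the 9 enamel genes in the table in each of the 3 Aire+/+ and 3 Aire−/− libraries (points), with the mean and SD of each genotype as lines. Amelx and Amtn stood at 42.7 and 36.3 CPM in the Aire+/+ libraries and at 0 in all Aire−/− libraries, while Tuft1 was at 9.62 and 9.61 CPM.

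Amtn, Ambn, Enam and Odam lie on chromosome 5 beside the casein genes, which encode milk proteins, and the salivary gene Smr3a. From the start of Csn1s1 (position 87666208) to the end of Ambn (position 88468531) every gene in the table but Csn2 had 4 or fewer UMIs over all 3 libraries labelled Aire−/−. Csn1s1 had 110 UMIs in the Aire+/+ libraries (45, 28 and 37) against 1, Csn1s2a had 170, 107 and 178 against 0, 0 and 3, and Smr3a had 29, 27 and 21 against 0. Csn3 (38, 15 and 34 UMIs against 1, 3 and 0) and the long non-coding RNA BC037156 (55, 50 and 73 against 0, 1 and 2) also fell, with edgeR adjusted p of 0.00313 and 2.9e-05. Csn2, which encodes beta-casein and lies between Csn1s1 and Csn1s2a (positions 87692624 to 87699630), rose from 457 ± 50.4 to 958 ± 143 CPM (log2 fold change 1.07, edgeR adjusted p = 0.000235). Some genes of this stretch were near the floor in the Aire+/+ libraries too, such as Cabs1 (8, 0 and 1 UMIs) and Prol1 (11, 4 and 14). On the far side of Enam, Jchain (log2 fold change -1.25, edgeR adjusted p = 0.229), Utp3 (-0.16, 0.598) and Rufy3 (0.26, 0.497) were not called. Before Csn1s1, Sult1e1 had 16, 9 and 16 UMIs in Aire+/+ against 0, 0 and 2, and Sult1d1 had 9, 2 and 5 against 0, 0 and 3. Neither carries a test, so the stretch is not shown to end at Csn1s1.

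**Figure D3:**
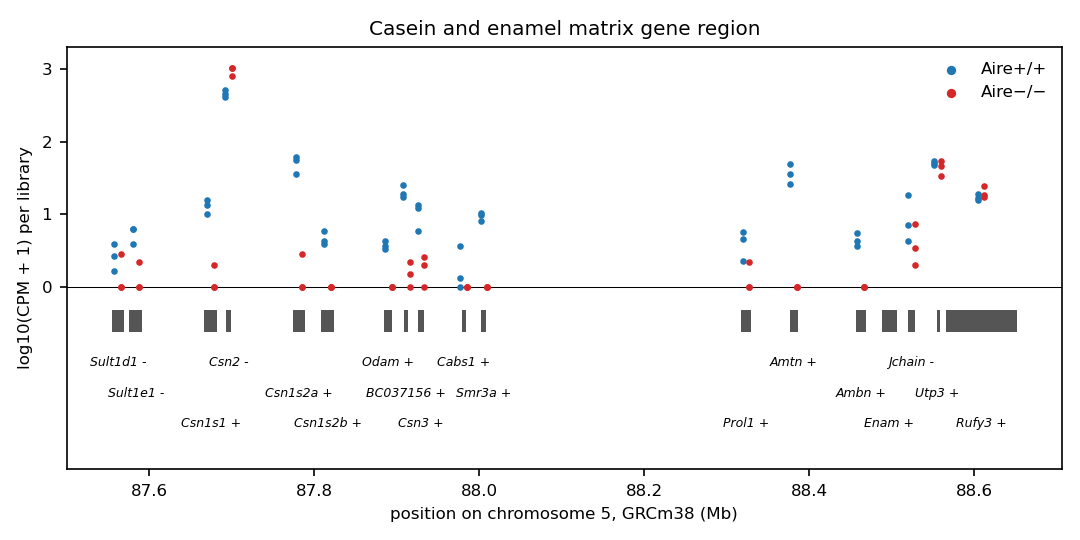
Genes of chromosome 5 around the caseins and enamel genes, drawn to scale as boxes by position (GRCm38, which is mm10, in Mb, horizontal axis), with the log10 of CPM + 1 (vertical axis) in each Aire+/+ library (blue) and Aire−/− library (red) as points above each gene in the table. Csn2 is the gene of this stretch that rose (457 to 958 CPM), while Csn1s1, Csn1s2a, Csn3, Smr3a and Amtn fell.

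Secreted proteins of exocrine glands fell in the libraries labelled Aire−/−. Among milk, lacrimal and salivary proteins 9 of 10 tested genes fell and Csn2 rose (9 and 1 adjusted over the list alone), with a median log2 fold change of -6.32, or -3.97 with genes at their bounds (camera adjusted p = 2.65e-07, adjusted p = 0.0955 with an estimated correlation). Wap, whey acidic protein, was at 24.4 ± 5.90 CPM against 0, at least 36.4-fold lower, and Csn1s2a had a ratio of 74.8 with a counting interval of 25.4 to 364. All 3 tested proteins of seminal vesicle and prostate fell (3 adjusted over the list alone; camera adjusted p = 4.53e-05, adjusted p = 0.0955 with an estimated correlation), with a median of -7.05, or -5.29 at the bounds. Sbp, spermine-binding protein, was at least 39.1-fold lower, and Spink1, a trypsin inhibitor, went from 229 UMIs over the Aire+/+ group (89, 74 and 66) to 1. All 3 tested major urinary and odorant-binding proteins fell as well (3 adjusted over the list alone; median -7.25, or -7.24 at the bounds; camera adjusted p = 4.53e-05, adjusted p = 0.0955 with an estimated correlation). Lcn3, a lipocalin, had 130, 107 and 149 UMIs against 1, 0 and 0. Mup6 fell from 92 UMIs to 1 (ratio 45.4, counting interval 7.95 to 1813) and is 90.7% to 95.3% identical to Mup2, Mup4 and Mup5 over its matching 3′ end.

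Hormones and enzymes known as autoimmune targets fell unevenly. Of 11 islet and type 1 diabetes genes 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 0.00203, adjusted p = 0.116 with an estimated correlation). Sst, somatostatin, went from 376, 472 and 440 UMIs to 0, 0 and 2, Ppy, pancreatic polypeptide, from 250 ± 41.8 to 1.02 ± 1.76 CPM, and Pyy, peptide YY, from 307 ± 41.6 to 6.32 ± 2.53 CPM. Ins2, insulin, had 110, 102 and 93 UMIs in the Aire+/+ libraries and 1, 0 and 0 in the Aire−/− libraries (edgeR adjusted p = 2.22e-06), while Gcg, glucagon, was at 28.7 ± 1.49 and 28.3 ± 5.80 CPM and was not called. Chga, chromogranin A, and Ptprn2, a phosphatase-like granule protein, rose, by 1.12 and 0.95 on the log2 scale. Among antigens of APS1, 8 of 14 tested genes fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 0.032, adjusted p = 0.285 with an estimated correlation), and the call was lost under scaling by library totals (adjusted p = 0.0614). Cyp1a2, a liver enzyme, fell from 416 UMIs (131, 131 and 154) to 1, Th, tyrosine hydroxylase, from 148 UMIs to 1 (ratio 73.0, counting interval 12.9 to 2904), and Bpifb1, a lung antigen, from 74, 72 and 106 UMIs to 1, 0 and 2. Cyp11a1, the enzyme that opens steroid synthesis, fell by 4.97, and a part of its 3′ end matches Tmem234, Tfdp2 and Thada at 90.6% to 91.6%. Hdc, histidine decarboxylase, and Ddc, aromatic amino acid decarboxylase, rose, by 0.79 and 0.93. The authors' deposited table gave Ddc an adjusted p of 0.144.

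Many plasma proteins of the liver fell in the libraries labelled Aire−/−. Of 19 tested, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -3.04 (camera adjusted p = 2.31e-07, adjusted p = 0.0955 with an estimated correlation). Apoa1, the main apolipoprotein of HDL, went from 143 ± 12.8 to 6.95 ± 9.35 CPM, Apoa2 from 54.9 ± 10.5 to 2.85 ± 1.78 CPM, and Ambp, a plasma protease inhibitor precursor, from 45, 60 and 46 UMIs to 0, 0 and 1. Alb, albumin, had 35, 31 and 48 UMIs in the Aire+/+ libraries and 0 in the Aire−/− libraries, while Crp, C-reactive protein, at 37.5 ± 8.05 and 45.5 ± 4.01 CPM, and Trf, transferrin, were not called. The antigens reported to depend on Fezf2, another regulator in these cells, did not pass as a group: 3 of 7 fell and 1 rose (3 and 1 adjusted over the list alone; median -0.66, camera adjusted p = 0.11). Apob (at least 21.4-fold lower), Krt10 and Fabp9 fell, and Col17a1 rose. Fezf2 itself was at 743 ± 92.0 and 672 ± 50.5 CPM and was not called.

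MHC class II genes were among the transcripts that rose. In the list of mTEC identity and antigen presentation 13 of 26 genes rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 0.000367, adjusted p = 0.0955 with an estimated correlation). H2-Ab1, an MHC class II chain, went from 11920 ± 1056 to 23570 ± 1978 CPM, Cd74, the invariant chain, from 14480 ± 1273 to 24120 ± 1507 CPM, and Relb, a transcription factor of the NF-kB family, from 273 ± 24.4 to 489 ± 63.3 CPM. Dendritic cells, B cells and cortical epithelium also carry MHC class II, and their part in this rise was not separated. H2-DMb1, a gene of the MHC class II pathway, rose by 1.38 on the log2 scale and is uncertain against its copy H2-DMb2 (92.6% identity). Ehf, an epithelial transcription factor, was the member that fell (-0.91, edgeR adjusted p = 0.0404), and Epcam, a surface marker of epithelium, was not called (edgeR adjusted p = 0.974). The chemokines and cytokines of these cells moved both ways without a call for the list: 6 of 16 fell and 3 rose (6 and 4 adjusted over the list alone; median -0.41, camera adjusted p = 0.442). Ccl20 fell by 2.11 and Xcl1 from 170 UMIs (44, 37 and 89) to 2, while Il15, a cytokine that sustains natural killer cells, rose by 1.29. Of the partners of Aire and the transcription machinery 3 of 20 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of -0.04 and a mean of 0.11, which differ in sign (camera direction up, adjusted p = 0.454). Dnmt3l, Hipk2, a kinase that phosphorylates AIRE (log2 fold change 1.12), and Hnrnpl (0.69), an RNA-binding protein, rose, and Prkdc, a DNA-dependent kinase, fell (-1.20).

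Cells of the medulla that mimic other tissues were represented by 8 lists, and their genes differed in direction. Genes of ciliated cells fell: 10 of 13 tested were lower and 0 higher (11 and 0 adjusted over the list alone; median -2.02, also with genes at their bounds; camera adjusted p = 2.19e-07, adjusted p = 0.0955 with an estimated correlation). Tekt1, a protein of ciliary microtubules, had 85, 120 and 100 UMIs against 1, 2 and 0, and Foxj1, the regulator of motile cilia, fell from 86.2 ± 19.2 to 29.4 ± 10.5 CPM. Genes of muscle fell, 11 of 15, and Des, desmin, rose (11 and 1 adjusted over the list alone; median -1.49; camera adjusted p = 0.00013, adjusted p = 0.0955 with an estimated correlation). Myl4, a myosin light chain, fell from 36.0 ± 2.96 to 5.47 ± 2.44 CPM, Myh8, a myosin heavy chain uncertain against Myh1, Myh2 and Myh4 (90.7% to 94.0% identity), was at least 26.8-fold lower, Des went from 262 ± 22.6 to 707 ± 45.5 CPM, and Myog, the regulator of muscle differentiation, at 5.97 ± 1.77 and 9.18 ± 1.38 CPM, was not called. Genes of keratinocytes fell, 12 of 21, and Grhl3 rose (12 and 1 adjusted over the list alone; median -1.06; camera adjusted p = 0.000762, adjusted p = 0.298 with an estimated correlation). Krt1, a keratin of differentiated skin, fell from 71.4 ± 11.6 to 8.78 ± 1.38 CPM and Krtdap, a protein of keratinocyte differentiation, by 1.58 on the log2 scale.

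Enterocyte and hepatocyte genes fell in 10 of 20 cases, and Cdx1, an intestinal regulator, rose (10 and 2 adjusted over the list alone; median -0.59; camera adjusted p = 0.00273, adjusted p = 0.0955 with an estimated correlation). Saa3, an acute-phase protein, went from 862 ± 108 to 129 ± 6.38 CPM (parts of its 3′ end match Ndufaf7 at 97.0% and Tmem131l at 96.6%), Reg3g, an antibacterial lectin, from 614 ± 68.4 to 166 ± 41.3 CPM, and Saa1, which shares 93.3% of its 3′ end with Saa2, from 140 ± 30.2 to 15.5 ± 11.0 CPM. Among ionocyte genes 3 of 8 fell and Kit rose (4 and 1 adjusted over the list alone; median -0.91; camera adjusted p = 0.032, adjusted p = 0.281 with an estimated correlation). Foxi1, the regulator of ionocytes, had 18, 15 and 19 UMIs against 0 and was at least 8.55-fold lower, and Cel, a pancreatic lipase in this list, was at least 17.6-fold lower. The ionocyte call was lost without the Aire+/+ library 753 (adjusted p = 0.0652). No call was made for the other 3 lists. Tuft cell genes rose in 3 of 16 cases and fell in 1 (7 and 2 adjusted over the list alone; median 0.50, camera adjusted p = 0.0551), with Gnb3, a taste transduction subunit, going from 24.4 ± 5.50 to 91.7 ± 40.9 CPM. Microfold cell genes fell in 3 of 11 cases (3 adjusted over the list alone; median -0.10, camera adjusted p = 0.258), among them Gp2, a receptor for bacteria, by 2.19 and Pglyrp1, a peptidoglycan-binding protein, from 970, 831 and 956 UMIs to 143, 294 and 249. Neuroendocrine genes rose in 4 of 9 cases and fell in 2 (6 and 3 adjusted over the list alone; median 0.68, camera adjusted p = 0.167), with Resp18, a granule protein, higher by 1.10, Insm1, a regulator, by 0.74, and Scg2, a granin, lower (-1.66).

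Interferon-stimulated genes fell in the libraries labelled Aire−/−. Of 28 members 23 fell, 2 rose and 3 were not called (25 and 2 adjusted over the list alone), with a median log2 fold change of -0.97 (camera adjusted p = 1.91e-08, adjusted p = 0.0821 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, went from 619 ± 5.27 to 181 ± 23.2 CPM (log2 fold change -1.78, standard error 0.14, edgeR adjusted p = 2.23e-06). Parts of the 3′ end of Isg15 match AC151275.1 at 95.6%, Olfr1307 at 90.7% and Gm42790 at 90.2%, which are not in the table. Ifi44 fell by 2.95 and Irf7, a transcription factor of the interferon response, by 1.51 on the log2 scale, and Ifit3 by 2.75, uncertain against its copy Ifit3b (94.3% identity). Cxcl10, a chemokine, and Irf1, a transcription factor, rose, by 0.79 and 0.91.

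Genes whose mutation impairs enamel without encoding matrix proteins did not move as a group. Of 17 tested members of the list of other amelogenesis imperfecta genes 3 fell and 2 rose (3 and 3 adjusted over the list alone), with a median of 0.09 and a mean of -0.10, which differ in sign (camera direction down, adjusted p = 0.972). Sp6, a transcription factor of ameloblasts, fell by 1.29, Lamb3, a laminin chain, by 0.71 and Fam83h, an ameloblast protein, by 0.80 on the log2 scale, and Col17a1, a collagen of epithelial anchoring, rose by 0.91 and Slc24a4, an ion exchanger, by 0.49. Of 5 dentin, bone and cement genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -1.71, camera adjusted p = 0.125). Bglap, osteocalcin, fell from 28.1 ± 11.7 to 1.63 ± 0.42 CPM and Bglap2 from 91 UMIs (19, 29 and 43) to 3, though their 3′ ends are 99.7% identical and match Bglap3 at 96.7% and 97.0%, and Spp1, osteopontin, fell by 1.71. The authors' deposited table gave Spp1 an adjusted p of 0.186. Smpd3, a sphingomyelinase, rose by 1.21.

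Markers of other cell types that a sort can hold moved as follows. Cortical epithelial genes rose in 7 of 11 cases (7 adjusted over the list alone; median 0.84; camera adjusted p = 0.00132, adjusted p = 0.236 with an estimated correlation), among them Tbata from 674 ± 65.8 to 1406 ± 35.2 CPM, Prss16, a thymus protease, by 1.20 and Ly75, an endocytic receptor, by 0.99. Thymocyte genes passed as a list with 1 of 19 members higher, Tcf7 (1 adjusted over the list alone; median 0.36; camera adjusted p = 0.032, adjusted p = 0.532 with an estimated correlation). Cd3e, at 4.09 ± 1.37 and 7.38 ± 1.75 CPM, and Cd6, at 13.0 ± 1.94 and 19.2 ± 2.30 CPM, were not called. Dendritic cell and macrophage genes passed with 5 of 19 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.31; camera adjusted p = 0.0465, adjusted p = 0.532 with an estimated correlation). Fcer1g, an Fc receptor chain, rose by 0.98, Batf3, a regulator of dendritic cells, by 0.87 and Cd209a by 1.38, Itgam, an integrin of myeloid cells, fell by 1.66, and the abundant C1qa was at 476 ± 113 and 613 ± 388 CPM. The thymocyte and the myeloid calls were also lost under several of the other settings. By mean log2 CPM of the list, the libraries of the genotypes overlapped for thymocyte genes (3.54 to 4.46 in Aire+/+, 3.92 to 4.60 in Aire−/−), and for the myeloid genes 749 (6.97) stood apart from the other 5 (6.02 to 6.27).

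Fibroblast and pericyte genes rose in 4 of 11 cases and fell in 1, without a call for the list (4 and 1 adjusted over the list alone; median 0.97, camera adjusted p = 0.076). Cspg4, a pericyte proteoglycan, went from 18.2 ± 2.30 to 80.1 ± 13.7 CPM and Fbn1, fibrillin, rose by 1.04, Rgs5 fell by 1.11, and Col3a1, a fibroblast collagen that was called higher, had 190, 69 and 14 UMIs in the Aire−/− libraries against 43, 22 and 17. The mean log2 CPM of the list was 6.18 in 746, against 5.24 and 4.86 in 748 and 749 and 4.64 to 4.93 in the Aire+/+ libraries, so 1 library largely carried the rise of that mean. Cspg4, Fbn1 and Dcn, also called higher, were nevertheless above every Aire+/+ library in each Aire−/− library. Endothelial genes fell in 2 of 8 cases (2 adjusted over the list alone; median -0.75, camera adjusted p = 0.111): Plvap by 2.06 and Ramp2 by 2.58, of which Ramp2 shares its last 300 nt with Vps25. B cell genes fell in 1 of 8 cases and rose in 1 (1 and 1 adjusted over the list alone; median -0.78, camera adjusted p = 0.463), Vpreb3 from 16.9 ± 0.63 to 1.92 ± 1.68 CPM and Pax5 from 3.86 ± 1.12 to 11.8 ± 2.30 CPM. Of erythroid genes 2 were tested, too few for a set test, and Car2 fell (1 adjusted over the list alone) while Alas2, at 19.8 ± 5.34 and 28.2 ± 5.26 CPM, was not called. Cell cycle genes fell in 2 of 17 cases, Rrm2 and Ccnb1 (2 adjusted over the list alone; median -0.28, camera adjusted p = 0.196), and Mki67, a marker of proliferation, was not called (edgeR adjusted p = 0.275). Immediate early and stress genes, which tissue dissociation can induce, rose in 5 of 22 cases (11 adjusted over the list alone; median 0.55; camera adjusted p = 0.000762, adjusted p = 0.397 with an estimated correlation), with Klf2 higher by 1.13, Fosb by 0.93 and Nr4a1 by 1.21 on the log2 scale. That call was lost by fry (adjusted p = 0.107), and the mean log2 CPM was 7.61 in 746, against 7.05 and 7.13 in 748 and 749 and 6.62 to 6.94 in the Aire+/+ libraries.

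Across the 31 lists, 30 had enough tested members for a set test. The camera test called 18 with the preset correlation and 0 with an estimated correlation, whose smallest adjusted p was 0.0821 and which gave 11 lists an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance and compares it with no other genes, called 19. These left out the thymocyte, myeloid and stress lists and took in the dentin, bone and cement genes, the Fezf2-dependent antigens, the chemokines and the microfold cell genes. Some genes stand in more than 1 list, such as Apob, Krt10, Col17a1, Chga and Ccl20. Of the called genes named here by the rule, Hipk2, Hnrnpl, Kit, Tcf7, Ccnb1, Lrmp, Cd209a, Nr4a1, Smpd3 and Pax5 lost their call under at least 1 other setting. Ehf, Ptprn2 and Slc24a4, list members called here, had adjusted p of 0.133, 0.0913 and 0.0852 in the authors' deposited table.

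**Figure D4:**
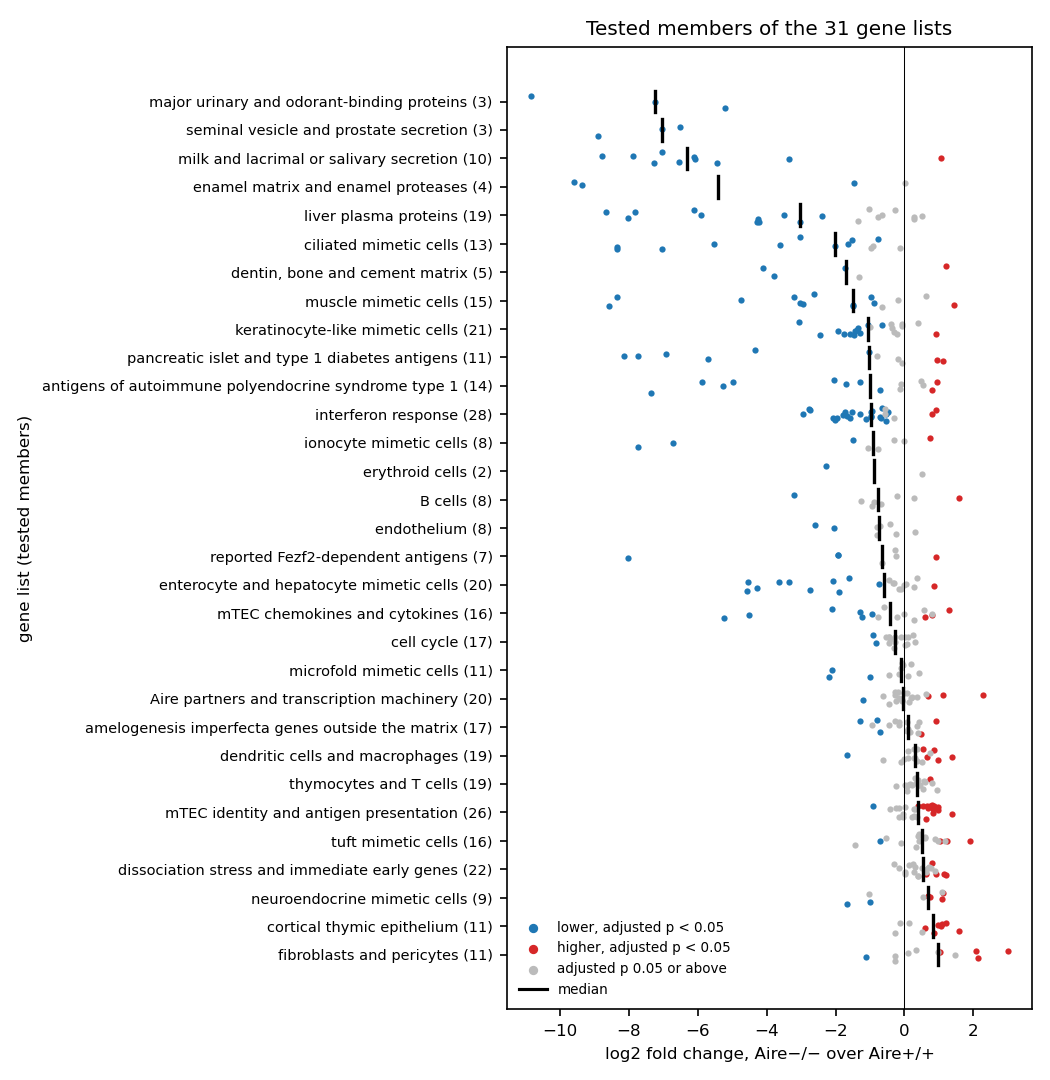
Log2 fold change of the Aire−/− over the Aire+/+ libraries (horizontal axis) of each tested member (points) of the 31 gene lists, as fitted by edgeR, with each list's median as a black line and genes called lower in blue, called higher in red and not called in grey. Medians run from -7.25 for major urinary and odorant-binding proteins to 0.97 for fibroblast and pericyte genes, a list highest in library 746.

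Among called genes expressed at low levels in these cells, most fell. When the tested genes were ranked by mean CPM and parted into 4 groups of 2989, the lowest group (2.15 to 9.33 CPM) had the largest share of decreases: 680 genes were called lower and 53 higher, so that 92.8% of calls were decreases (exact 95% interval 90.6 to 94.5). That share was 71.7% in the next group (9.33 to 20.7 CPM), 44.8% in the one after (20.7 to 51.7 CPM) and 24.4% in the highest (51.7 to 19300 CPM), where 174 were lower and 539 higher. The interval for the lowest group takes called genes as independent and covers no spread between libraries. The mean used for ranking covers both genotypes, so a gene's own change moves its rank. Ranked by the mean of the higher genotype, a choice made after seeing the data, the shares were 92.7%, 79.6%, 50.7% and 28.5%. These shares come from counts that were not thinned. At the same CPM the deeper Aire+/+ libraries hold more UMIs, so at low levels a fall can be easier to call than a rise. The shares were not taken at equal depth, so the part of depth in them was not tested. When every library was thinned to 1014581 UMIs, 15214.6 ± 62.1 genes were detected in the Aire+/+ libraries and 13605 ± 34.3 in the Aire−/− libraries (SD, n = 3 each), a difference of -1609.6 genes with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow. Equal totals leave a typical gene more UMIs in the Aire+/+ libraries, whose TMM factors were 1.03 to 1.11 against 0.90 to 0.96. Thinned to equal effective sizes, a choice made after seeing the data, the difference was -1496.5 genes. The table lists only genes that reach 6 UMIs in at least 1 library, so genes below that in all 6 are outside these counts. Deeper libraries reach 6 UMIs more easily, so this set of genes favours the Aire+/+ libraries (2736932 to 2887321 UMIs against 1014581 to 1960802). Thinning does not undo that, so the size of the difference cannot be taken as that over all genes.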

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

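Thinning to the smallest total, leaving out Aire+/+ 753 and Aire−/− 746 together, detection from 6 UMIs, thinning to equal effective sizes and ranking by the higher genotype were chosen after seeing the data, and the other alternatives were fixed before the data were examined. For the covariate of Xist and Y-linked transcripts, the split (Xist above 5 CPM, in 745 and 746, where Eif2s3y was lowest) was also set after seeing the data.

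The count of lower genes (1450) stayed within 1.5 times under other scalings and tools (1436 to 2048), with single libraries left out (1098 to 1899) and with the Xist covariate (1393), and moved to 867 with min.count 30 and 831 after thinning, where fewer genes were tested (8154 and 9244 against 11956). The count of higher genes (1027) was more sensitive. It was 567 with library totals alone, where the median of all genes was -0.22, against 823 under upper-quartile scaling, 1015 under RLE, 829 by DESeq2 and 1040 by limma-voom. It was 574 after thinning, with fewer UMIs and genes, 359 at 2-fold or more and 542 at an adjusted p of 0.01, where the threshold was stricter. Leaving out single libraries gave 618 to 1156 higher genes, with 632 without Aire+/+ 745 and 618 without Aire+/+ 753, and leaving out 753 and 746 together gave 652, in each case with fewer samples. Genes lower by at least 8-fold (557) ranged from 247 with min.count 30 to 1129 without a filter. Those higher by as much (5) ranged from 2 to 11. No gene called here had the opposite sign under any of these fits. The share of decreases in the lowest of the 4 groups by expression (92.8%) was 97.1% with min.count 3, which tests more genes at low counts. It was 96.1% with library totals alone, where the median of -0.22 moved all genes toward decreases, and 92.7% when ranked by the higher genotype.

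The fold change of Aire in the libraries labelled Aire−/− ranged from 0.91 to 1.16 over all alternatives. The difference in genes detected at equal depth ranged from -1911.8 (detected from 2 UMIs) to -1359.3 (without Aire−/− 746), always at an exact permutation p of 0.1, which says nothing about stability. It was -1605.6 with detection from 6 UMIs and -1496.5 with equal effective sizes. Each count covers only genes in the deposited table, a set that favours the deeper Aire+/+ libraries.

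The number of gene lists called (18) fell to 0 when camera estimated the correlation between genes, which gave 11 lists an unadjusted p under 0.05, while fry called 19, with 4 lists gained and 3 lost. The enamel list then had an adjusted p of 0.0955, against 4.12e-06 to 0.00256 under the other alternatives of camera and 6.57e-05 by fry. Correlation above the preset 0.01 is argued against as the cause for the interferon list and the enterocyte and hepatocyte list. Their estimated correlations were 0.004 and -0.016, yet camera's unadjusted p rose from 6.37e-10 to 0.00274 and from 0.00127 to 0.0246. A simulated list of changed genes, drawn independently, went from a camera p of 3.95e-37 to 0.000173. In the other called lists the estimate was above 0.01, and its part in their losses was not tested. Of the 29 other lists with a test, 16 kept their direction and side of the threshold under every alternative but the estimated correlation that gave them a value. The lists of thymocytes and of dendritic cells and macrophages were lost most often. The first was lost without Aire+/+ 750 (adjusted p = 0.249), Aire+/+ 753 (0.0606) and Aire−/− 748 (0.0692), the second without Aire+/+ 753 (0.0911) and Aire−/− 749 (0.426), and both with min.count 30 (0.126), after thinning (0.241 and 0.233) and by fry (0.446 and 0.418). The ionocyte list was lost without Aire+/+ 753 (0.0652) and after thinning (0.113), the APS1 antigens with library totals alone (0.0614), and the stress genes by fry (0.107).

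The list of amelogenesis imperfecta genes outside the matrix turned from down to up without a filter (adjusted p = 0.703), with min.count 3 (0.804) and without Aire+/+ 750 or any 1 Aire−/− library (0.629 to 0.968), and Tuft1 turned negative under upper-quartile scaling (-0.034), with library totals alone (-0.172), with the Xist covariate (-0.007) and without Aire+/+ 745 (-0.174), Aire−/− 748 (-0.011) or Aire−/− 749 (-0.024), within a range of -0.174 to 0.231 over single libraries left out. Neither was called under any of these, and the cause was not tested. Of 104 called named genes (111 tested, Aire aside), 93 kept direction and side of the threshold under every alternative that tested them. With min.count 30, 95 of the 111 were tested, and after thinning 98. Without Aire+/+ 745 the calls of Hipk2 (edgeR adjusted p = 0.0721), Hnrnpl (0.0583), Kit (0.0876) and Ccnb1 (0.0761) were lost, and without Aire+/+ 753 those of Hipk2 (0.069), Hnrnpl (0.0851), Kit (0.0852), Tcf7 (0.0802) and Ccnb1 (0.088). Without Aire−/− 748 those of Lrmp (0.0542), Kit (0.081), Tcf7 (0.0912) and Ccnb1 (0.0551) were lost, and without Aire+/+ 750 that of Nr4a1 (0.0509).

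Depth limits the genes that are low in both genotypes. In the simulated data edgeR recovered 35% of genes made 2-fold lower, so genes not called are not shown to be equal.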

Other observations

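The tests of gene families, both tests of Mir692-1, the tests of myeloid markers and of Ifnb1, the test of genes near Aire and the thinning of every library were chosen only after the results they concern were seen.

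Symbols that share a stem were counted as families. Of 201 families with at least 8 tested members, 13 held more lower genes than a draw from all tested genes gives (Fisher's exact test, adjusted over 402 tests) and 0 held more higher genes, where 9 had an unadjusted p under 0.05. Kallikreins (Klk) were lower in 21 of 22 cases (median log2 fold change -3.82, adjusted p = 3.96e-16), late cornified envelope genes (Lce) in 14 of 15 (2.51e-10), cilia and flagella genes (Cfap) in 12 of 16 (1.11e-06), beta-defensins (Defb) in 9 of 10 and oligoadenylate synthetases (Oas) in 9 of 10 (3.32e-06 each), and Sprr genes in 8 of 11 (0.000272). The families of Klk, Lce, Cfap, Defb, Sprr, Ifi (7 of 11) and Ces (6 of 10) had 0 higher members under each scaling. These tests take the members of a family as independent, so their p-values measure no spread between libraries. They also compare with all tested genes (1450 of 11956 lower), not with genes of like expression. In the lowest of the 4 expression groups 680 of 2989 were lower.

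Keratins (Krt) were lower in 23 of 38 cases (adjusted p = 2.51e-10), while Krt8 (0.82), Krt18 (0.40), Krt78 (0.66) and Krt79 (1.57) were higher, and the count of higher keratins was 3 under upper-quartile scaling and 2 with library totals alone. Prss proteases were lower in 9 of 12 cases and Prss16 higher, Serpinb inhibitors lower in 8 of 14 and Serpinb2 higher (1.91), and Ly genes lower in 9 of 18 with Ly75 and Ly9 higher, and each family had as many higher members under each scaling. Carbonic anhydrases (Car) were lower in 7 of 11 cases, and Car7 was higher, a call lost under upper-quartile scaling and library totals alone. Near-identical copies were not searched for most members of these families.

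Genes lower by at least 8-fold outnumbered genes higher by as much, by 557 to 5 as fitted, and by 537 to 4 with pooled UMIs and 3 UMIs as the floor of each genotype. With single libraries left out the fitted counts were 539 to 854 lower and 4 to 10 higher. Deeper Aire+/+ libraries are argued against as the whole cause, since 293 lower and 4 higher genes were that strong after every library was thinned to the smallest total, 278 and 3 of them among the 557 and 5, and all 293 and 4 reached 8-fold with that floor. The limit of 6 UMIs in the deposited table is argued against by the 356 lower and 4 higher genes among the 9422 genes at 10 CPM or more in the higher genotype, which is above the 6.16 CPM that 6 UMIs make in the shallowest library. The choice among the scalings used is argued against by at least 557 such genes under each of 3 other scalings, with at most 5 higher. These moved the median log2 fold change of all genes from -0.023 to between -0.024 and -0.221, each toward decreases. A scaling error common to all of them is not covered. A difference between the genotypes as labelled may explain the pattern and stays a hypothesis, since it was found and tested on the same libraries.

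Mir692-1 had 52 UMIs over the Aire+/+ group and 8304 over the Aire−/− group. A constant share of reads from the ferritin light chain transcript Ftl1 is argued against, because Mir692-1 had 0.102 UMIs per 100 of Ftl1 in the Aire+/+ libraries and 14.2 in the Aire−/− libraries, a 139-fold difference, while Ftl1 rose by a log2 fold change of 1.21 (edgeR adjusted p = 4.19e-05). A sequence variant of a ferritin copy in the Aire−/− mice might move reads to Mir692-1, which is 97.8% identical to Ftl2-ps, 96.8% to Gm12164 and Gm15590 and 95.7% to Ftl1. This stays open because reads were not analysed here and the first 3 are not in the table. A biological rise of the microRNA gene also stays open and was not tested.

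Interferon response genes were lower in the libraries labelled Aire−/− (23 of 28). Fewer dendritic cells and macrophages in those sorts would lower their 19 tested markers, which share 0 genes with the interferon list. The median log2 fold change of these markers was 0.31 (quartiles 0.11 and 0.61, with 1 lower and 5 higher). That rise rests on Aire−/− 749, where the mean log2 CPM of the markers was 6.97, against 6.02 and 6.20 in 746 and 748 and 6.10 to 6.27 in the Aire+/+ libraries. Without 749 the median was -0.10 (quartiles -0.42 and 0.44, camera adjusted p of the list 0.426), still above the -1.15 of the interferon genes, which were at 5.44 to 5.56 in all 3 Aire−/− libraries and 6.56 to 6.72 in the Aire+/+ libraries. A loss of these cells as large as the interferon decrease is argued against, and a smaller loss stays open. Depth is argued against by 20 of 28 members lower after thinning. Under 3 other scalings 23 to 26 were lower. Each of these moved the median of all genes toward decreases, so they cannot exclude a scaling error common to all. Loss of interferon transcripts made by the cells could contribute, since Ifnb1 had 26 UMIs over the Aire+/+ group and 1 over the Aire−/− group and Ifng 4, 7 and 18 UMIs against 0, 0 and 3, but these counts are too few to decide it. The interferon lambda genes Ifnl2 (16.1 ± 3.55 and 17.6 ± 12.3 CPM, edgeR adjusted p = 0.996) and Ifnl3 (11.1 ± 4.68 and 16.1 ± 14.5 CPM, 0.669) were not called.

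Genes that fell may lie next to each other more often than genes of like expression. Of 11144 neighbouring tested pairs, 208 had both genes lower, against a mean of 164 over 10000 permutations within 20 bins of expression (ratio 1.26, one-sided permutation p = 2e-04, highest permutation 208). Pairs whose symbols share a stem had been left out. Copies under other symbols were not.

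Strain differences around the targeted gene could alter genes close to Aire. Within 5 Mb of Aire, 27 of 151 genes were called (17.9%), against 20.7% elsewhere (two-sided Fisher's exact p = 0.42, odds ratio 0.833, 95% interval 0.527 to 1.27), which does not exclude an excess. Within 0.5 Mb, 3 of 13 were called, all higher: Dnmt3l (2.27), Icosl (0.64, edgeR adjusted p = 0.00234) and Cstb (0.72, 0.00443). An effect on these genes stays open.

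The 6 libraries form 10 splits into 3 and 3, which cannot give a share under 0.05. The real split gave 2477 genes by edgeR and the highest other 0, where the other splits had 90 to 681 genes at an unadjusted p under 0.05 and the real one 3768, and 1 of 10 splits reached the real count. For gene lists the real split gave 18, again with 1 of 10 reaching the real count. The other splits called 3 to 12 lists, though each called 0 genes. The split with 12 set 745, 746 and 748 against the rest. Each other split mixes both genotypes in both of its groups, in unequal numbers. Part of a genotype difference then adds to the spread within groups, which lowers the calls. Another part stays between the groups and can raise the calls of lists. The comparison of splits therefore cannot tell how many calls chance alone would give.

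Single libraries differed in a few genes. Rps2 had 168 UMIs in Aire+/+ 753 and 2919 to 5142 in the others, and Gapdh 90 in 753 and 28 in 746. Dcn had 294 UMIs and Upk3b 98 in Aire−/− 746, and Xist had 70 in Aire+/+ 745 and 6 or fewer in the others.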
